A study of Mus musculus with 8 samples.

How the data were processed

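Messenger RNA was measured in 8 pieces of mouse pancreatic tumour derived from the KPC model, in which pancreatic cells carry activated Kras and mutant Trp53. The 4 RFA pieces were taken 48 h after radiofrequency ablation at 15 W for 10 s, and the 4 control pieces, labelled with the same 48 h, were untreated. Libraries were made with the QuantSeq 3' kit, which sequences the 3' end of polyadenylated transcripts, per the labels' protocols. Each library therefore reports on gene ends, and a transcript's length has little part in its count.

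The authors trimmed reads with cutadapt 1.15 and quantified genes with RSEM 1.3.1 against mouse build GRCm38 (mm10), per the submitters' processing notes. The aligner, the annotation release and the strand setting are not given in the sources used here. The deposited files hold, per the file headers, an expected count, a TPM and an FPKM value for each of 47069 genes. Expected counts are RSEM's estimates and need not be whole, since a read that matches several genes is divided among them. TPM and FPKM as deposited by the authors are scaled for gene length, which does not suit 3' reads. TPM was used only as an alternative and FPKM was not used. Copies that share reads, such as the Amy2a amylase genes and Hspa1a with Hspa1b, are uncertain as single genes, as are overlapping antisense genes. Of the gene identifiers, 46488 matched a symbol in the reference table, and coordinates came from the GENCODE annotation of the same build.

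Groups and replicate numbers came from the sample titles. Expected counts were rounded to whole numbers. Total counts ran from 6098708 to 6750410 per library. Shares of counts carry Wilson 95% intervals no wider than 0.037 percentage points to either side for the acinar list and 0.026 for mitochondrial genes. These intervals cover counting error only, since no molecular identifiers were described. Genes were kept by edgeR's filterByExpr with a minimum count of 10 and a minimum total of 15, which left 13008 genes. They were tested by edgeR 4.0.16 quasi-likelihood (robust, TMM scaling, group as the only term, 6 residual degrees of freedom) with Benjamini-Hochberg adjustment and a false discovery rate (FDR) threshold of 0.05. Standard errors of log2 fold changes are the fold change over the square root of its F statistic. Per-library levels are TMM-scaled CPM, the count scaled to a common library size. Principal components used log2 CPM with a prior count of 2 on the 500 most variable genes. Single measures were compared by an exact two-sided permutation test over the 70 arrangements of 4 against 4, whose smallest p is 0.0286. With a library left out fewer arrangements remain, so the exact p moves in coarser steps.

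Before the data were examined, 34 gene lists with 467 members were written from textbook knowledge, covering tumour, stroma, immune and other cell types, stress and immune pathways, and mitochondrial transcripts. The 28 lists with at least 5 tested members were compared with all other genes by camera (limma 3.58.1) with a preset inter-gene correlation of 0.01. Camera with an estimated correlation and fry were alternatives. The genes to be named were also fixed by rule: the genes of largest change among those past the threshold or, as none passed, the 5 with the smallest p in each direction, up to 4 members of each list by p, and 15 genes of immune, tumour and stress interest. In the text, called lists show at most 4 such members and other lists at most 2, a limit set after the values were seen.

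Alternatives fixed in advance were RLE, upper-quartile and library-size-only scaling, DESeq2 1.42.0, limma-voom with quality weights, no filter, a filter of 1 CPM in 4 libraries, unrounded counts, limma on log2(TPM + 1), thinning to the smallest library, a replicate block, stricter thresholds and leaving out each library in turn. Others were added after the values were seen. They were the log2 acinar share as a covariate, removal of 77 exocrine genes before scaling, and leaving out RFA libraries 3 and 4 with or without control library 3. The acinar share did not overlap between the groups, so the fit with it as a covariate cannot separate group from share. All ran under R 4.3.3. On simulated RFA and control libraries built from the means, sizes and dispersions of the 13008 tested genes, the edgeR step called 5.97% of genes changed 2-fold, 68.7% of those changed 4-fold and 95.5% of those changed 8-fold. It called 1 unchanged gene. A raised list of 15 genes was called, along with 1 other list. The simulated genes varied independently of each other, without the shared differences in tissue content of the real libraries. The rates therefore need not hold for the real libraries. Nor can the list check show how often camera calls lists of correlated genes falsely.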

Results

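RNA from 4 ablated and 4 untreated KPC-derived pancreatic tumours was profiled 48 h after treatment, to ask how local ablation altered expression in the tumour tissue. Radiofrequency ablation (RFA) destroys tissue by heat from an alternating current. Total counts ran from 6098708 to 6750410 per library and did not differ between groups beyond their spread (exact permutation p = 0.286). The labels do not say whether replicates came from separate animals, so p-values measure the spread between these samples only.

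Transcripts of pancreatic acinar cells, the enzyme-secreting cells of normal exocrine pancreas, were lower in every RFA library than in any control. The 14 genes of the acinar list made up 30.9% ± 8.44 of counts in controls and 4.553% ± 5.434 after RFA (SD, n = 4 each, exact two-sided permutation p = 0.0286, the smallest that 70 arrangements allow). Controls held between 19.0% and 38.6%. RFA replicates 1 and 2 held 11.01% and 7.09%, while replicate 4 held 0.104% (Wilson 95% interval 0.101% to 0.106%) and replicate 3 held 0.00876% (0.00804% to 0.00953%). The acinar list fell (14 of 14 members with a negative log2 fold change, median -4.75, camera adjusted p = 5.9e-12), and adjusted p = 0.618 with an estimated correlation. Without RFA replicates 2, 3 or 4 in turn the difference in share had an exact permutation p = 0.0571, although every remaining RFA library still lay below every control.

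Among its members, pancreatic elastase Cela1 went from 41330 ± 38050 CPM in controls to 849.5 ± 972.7 after RFA (log2 fold change -5.60 ± 1.83 SE, edgeR FDR = 0.216). Carboxypeptidase Cpa2 (-4.995 ± 1.82), the lipase cofactor Clps (-5.29 ± 1.96) and pancreatic lipase Pnlip (-5.72 ± 2.15) had FDR values of 0.244, 0.249 and 0.255. In edgeR 0 of the 14 passed the threshold over all genes and 0 adjusted over the list alone, while 10 had an unadjusted p under 0.05 and 13 had all RFA libraries below all controls. DESeq2 called 5 of them lower over all genes, these 4 and the trypsin Try4. The 10 genes with the largest counts in each library took 43.1% ± 10.5 of control counts and 17.6% ± 4.63 of RFA counts (SD, n = 4 each, exact permutation p = 0.0286). Genes with at least 1 count numbered 15254 to 18838 in controls and 18934 to 19123 after RFA (exact permutation p = 0.0286, and p = 0.0571 without any 1 RFA library).

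**Figure D1:**
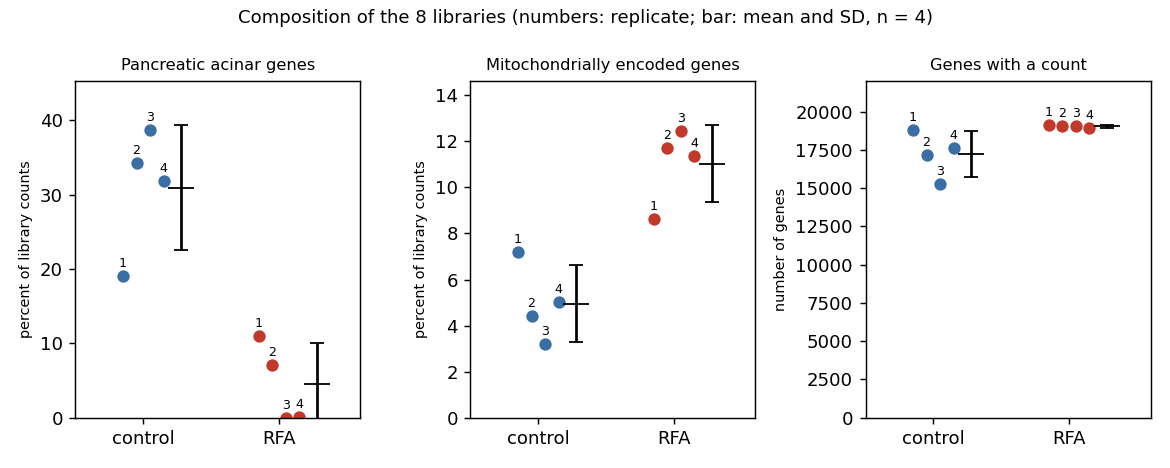
Percent of library counts from the 14 acinar genes, percent from mitochondrially encoded genes, and number of genes with a count (vertical axes), for each control and RFA library (points, numbered by replicate), with mean and SD (bars, n = 4, drawn to 0 where they would pass below it). Acinar shares lie between 19.0% and 38.6% in controls and between 0.00876% and 11.01% after RFA.

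On the first principal component, which held 72.7% of the variance, control scores ran from -73.7 to -8.03 and RFA scores from -3.05 to 79.0 (exact permutation p = 0.0286). Control 1 lay next to RFA 1 and RFA 2, control 3 lay at the low end, and RFA 3 and RFA 4 lay at the high end. The scores rose in the order in which the acinar share fell, over all libraries and within each group. Group and acinar share cannot be told apart along this component. The exact p was 0.0571 with all tested genes in place of the 500 most variable, 0.0857 without control replicate 3, and 0.0571 without control replicates 1, 2 or 4 or RFA replicates 3 or 4.

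**Figure D2:**
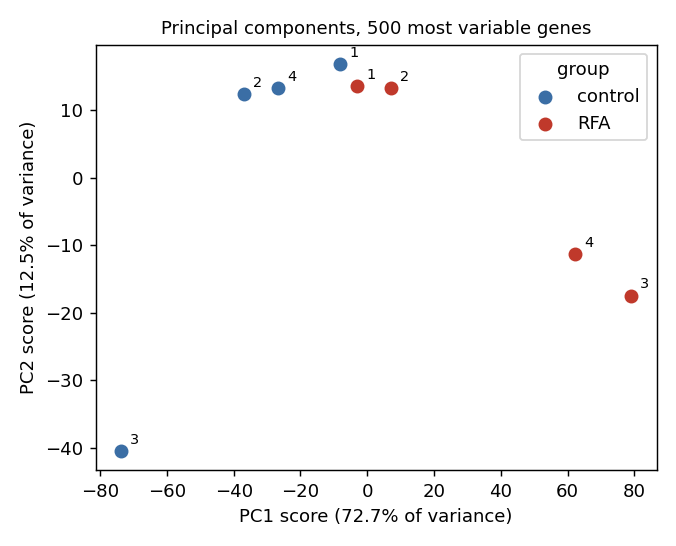
Scores of the 8 libraries on the first component (horizontal axis, 72.7% of variance) and second component (vertical axis, 12.5%), coloured by group and numbered by replicate. The first component orders the libraries by falling acinar share and parts the groups, with control replicate 1 at -8.03 and RFA replicate 1 at -3.05 adjacent.

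Gene by gene, no difference between ablated and untreated tumours reached the threshold in edgeR. The smallest p belonged to the exocrine elastase Cela3a among lower genes, and to the platelet chemokine Ppbp and the gastric gene Gkn3 among higher genes. Of 13008 genes tested, 0 were higher and 0 were lower at FDR under 0.05, the smallest FDR being 0.184, while at an unadjusted p under 0.05 there were 630 higher and 1488 lower. DESeq2 called 67 higher and 584 lower, and limma-voom 64 and 630. The tools shared 37 of the higher genes and 421 of the lower ones. All RFA libraries stood above all controls for 575 genes and below them for 773, together 10.4% of genes. The mean expected by chance is 2.86%, but the share under other divisions of the libraries was not computed, so chance was not excluded. Scaling by library size alone moved the median log2 fold change from 0.04 to 1.41 and called 5460 genes higher and 58 lower. Without control replicate 1, edgeR called 10 higher and 262 lower.

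The higher genes with the smallest p, all missing the threshold at FDR = 0.184, were these, with positions on mouse build GRCm38. Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063) went from 0.754 ± 0.52 to 4.91 ± 2.03 CPM (log2 fold change 2.52 ± 0.52 SE). Gkn3 (ENSMUSG00000030048, chromosome 6, 87383256 to 87388935) went from 1.13 ± 0.91 to 7.18 ± 3.37 CPM (2.44 ± 0.55 SE). Smaller differences were seen in the splicing factor Prpf19 (ENSMUSG00000024735, chromosome 19, 10895231 to 10909559, 0.81 ± 0.19 SE), the circadian repressor Nr1d2 (ENSMUSG00000021775, chromosome 14, 18204054 to 18239127, 0.66 ± 0.15 SE) and the membrane protein Tmem98 (ENSMUSG00000035413, chromosome 11, 80810175 to 80822033, 0.87 ± 0.20 SE). Each of these 5 genes was past the threshold in DESeq2, with Nr1d2 at an adjusted p of 0.00236.

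The lower genes with the smallest p were also at FDR = 0.184. Cela3a (ENSMUSG00000078520, chromosome 4, 137401554 to 137409791) had 338 counts in controls and 11 after RFA (log2 fold change -6.61 ± 0.94 SE). Ranbp3l (ENSMUSG00000048424, chromosome 15, 8967949 to 9067335) had 107 and 3 counts. After TMM scaling the ratio of RFA to control was 0.011, with a counting interval of 0.00223 to 0.0329. The dehydrogenase family member Sdr9c7 (ENSMUSG00000040127, chromosome 10, 127898518 to 127911761) had 129 and 4 counts. The water channel Aqp8 (ENSMUSG00000030762, chromosome 7, 123462291 to 123468004) stood at -3.61 ± 0.62 SE, and the unclassified locus Gm43290 (ENSMUSG00000104641, chromosome 5, 65476505 to 65478061) at -1.79 ± 0.31 SE. All 5 had all RFA libraries below all controls, and all 5 were past the threshold in DESeq2 and in edgeR without control replicate 1 (FDR = 0.0328).

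**Figure D3:**
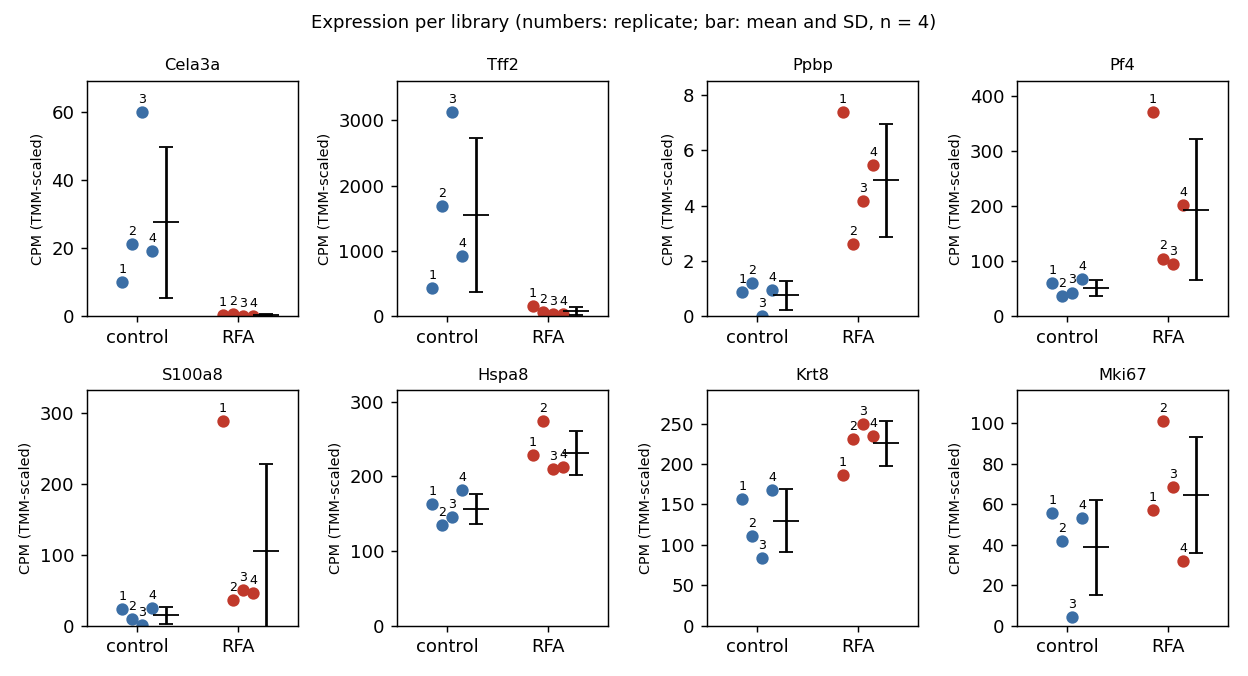
TMM-scaled CPM (vertical axes, linear from 0) of 8 genes in each control and RFA library (points, numbered by replicate), with mean and SD (bars, n = 4, drawn to 0 where they would pass below it). All RFA libraries lie below all controls for Cela3a and Tff2 and above them for Ppbp, Pf4, S100a8, Hspa8 and Krt8, while Mki67 overlaps.

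The lists of neutrophils and of acute inflammation rose after ablation by camera with the preset correlation. The neutrophil list rose (11 of 11 tested members with a positive log2 fold change, median 1.46, camera adjusted p = 7.24e-05), and adjusted p = 0.618 with an estimated correlation. Its leading members were the collagenase Mmp8 (log2 fold change 3.05 ± 0.84 SE, FDR = 0.193), the iron-sequestering Lcn2 (3.18 ± 0.98, FDR = 0.204) and the calprotectin subunits S100a8 (2.79 ± 0.91, FDR = 0.216) and S100a9 (2.53 ± 0.93, FDR = 0.246). In edgeR 0 passed over all genes, 5 had an unadjusted p under 0.05 and 3 passed adjusted over the list alone, while DESeq2 called Mmp8 and Lcn2 over all genes. Summed over the list, CPM was 57.4 ± 36.2 in controls and 268 ± 277 after RFA (SD, n = 4 each, exact permutation p = 0.0286). RFA replicate 1 held 684 CPM and the other 3 RFA libraries 129 ± 9.75 (SD, n = 3), so that without it the ratio of RFA to control means went from 4.67 to 2.25. Acute inflammatory cytokines and chemokines rose (13 of 13, median 1.35, camera adjusted p = 0.000142), and adjusted p = 0.618 with an estimated correlation. The neutrophil attractants Cxcl2 (1.83 ± 0.60) and Cxcl3 (1.86 ± 0.77), the monocyte attractant Ccl2 (1.71 ± 0.69) and the prostaglandin synthase Ptgs2 (1.39 ± 0.64) had FDR values of 0.216, 0.283, 0.278 and 0.325. In edgeR 0 members passed over all genes or adjusted over the list alone, with 3 at an unadjusted p under 0.05, while DESeq2 called Cxcl2 over all genes. Il6 did not pass the expression filter and was not tested, with 18 counts in controls and 164 after RFA (TMM-scaled means of 1.002 and 3.834 CPM). Ly6g did not pass either, with 1 and 25 counts (ratio 9.78 after TMM scaling, counting interval 1.6 to 402). The inflammatory list summed to 104 ± 81.5 CPM in controls and 249 ± 131 after RFA (SD, n = 4 each, exact permutation p = 0.0857), and its call was lost by library size only (adjusted p = 0.126). Adjusted over all lists, the lowest exact permutation p of the summed CPM was 0.162. The acinar share given above also parted the groups, and within the RFA group replicate 1 held the highest acinar share, 11.01%, as well as the highest neutrophil sum.

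The monocyte and macrophage list rose (15 of 15, median 0.51, camera adjusted p = 0.00752), with adjusted p = 0.828 with an estimated correlation, and it was not called without RFA replicate 1 (adjusted p = 0.264) or by library size only (adjusted p = 0.319). Cd14, an endotoxin co-receptor, stood at 1.29 ± 0.53 SE (FDR = 0.281), the complement subunits C1qc at 0.68 ± 0.34 (FDR = 0.354) and C1qa at 0.48 ± 0.27 (FDR = 0.388), and Apoe at 0.44 ± 0.24 (FDR = 0.375). Adgre1, which encodes F4/80, stood at 0.42 ± 0.46 SE (FDR = 0.637). The list of alternative activation was not called by camera (median 0.58, camera adjusted p = 0.243). Retnla stood at -2.65 ± 0.57 (FDR = 0.184) and was the only member to pass adjusted over the list alone and the only one that DESeq2 called, while Chil3 stood at 2.43 ± 0.81 (FDR = 0.221) and arginase Arg1 at 1.72 ± 0.79 (FDR = 0.322). The list was called higher without RFA replicate 3 (adjusted p = 0.0363). Arg1 was at 52.0 ± 50.3 CPM in controls and 173.5 ± 65.9 after RFA, with all RFA libraries above all controls. Of 4 tested platelet genes, too few for the list test, 2 passed adjusted over the list alone, Ppbp and Pf4 (1.89 ± 0.45 SE, FDR = 0.184 over all genes).

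Lymphocyte and dendritic cell lists were not called with all 8 libraries. The T cell list had a median of -0.10 and a camera adjusted p = 0.791 in the direction up, so its median and test differed in sign. Cd8b1 (0.50 ± 0.98 SE, FDR = 0.805), Cd3g (-0.47 ± 0.97, FDR = 0.819) and Cd8a (0.08 ± 1.01, FDR = 0.978) lay within the spread. Cd3e and Foxp3 did not pass the expression filter, with 24 and 23 counts in controls and 48 and 49 after RFA. After TMM scaling Cd3e had a mean of 1.081 CPM in controls and 1.204 after RFA, and Foxp3 0.854 and 1.137. Of the cytotoxic effectors 3 were tested, among them Klrd1 (-0.70 ± 0.70, FDR = 0.604) and Ccl5 (-0.33 ± 0.77, FDR = 0.842). Regulatory T cell and checkpoint genes (median 0.35, camera adjusted p = 0.357), with Tnfrsf9 (0.38 ± 0.34, FDR = 0.558) and Vsir (0.40 ± 0.35, FDR = 0.563), were not called. Cd274, the PD-L1 gene, stood at 0.57 ± 0.66 SE (FDR = 0.658). B and plasma cells (median -1.10, camera adjusted p = 0.143) included Cr2 (-0.73 ± 0.48, FDR = 0.445) and Ms4a1 (-1.12 ± 0.84, FDR = 0.497). That list was called lower without control replicates 2 or 3 or RFA replicate 3 (adjusted p of 0.0117, 0.0409 and 0.0302). Dendritic cell genes (median 0.16, camera adjusted p = 0.758) held Zbtb46, which was lower in all RFA libraries than in all controls (-1.14 ± 0.30, FDR = 0.184) and passed adjusted over the list alone and in DESeq2, Fscn1 (1.09 ± 0.43, FDR = 0.268) and Itgax (-0.05 ± 0.40, FDR = 0.965). Of 3 tested mast cell genes Kit stood at -1.16 ± 0.70 (FDR = 0.416) and Cpa3 at -0.66 ± 0.52 (FDR = 0.512). Of 4 eosinophil genes Il5ra stood at 1.20 ± 0.93 (FDR = 0.506) and Ccr3 at 0.69 ± 0.63 (FDR = 0.572).

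Interferon and MHC genes were likewise uncalled with all 8 libraries. Camera adjusted p was 0.845 for the type I interferon response, whose median of 0.17 and mean of 0.08 were positive while the test pointed down. It was 0.689 for the interferon gamma response (median 0.20), 0.845 for MHC class I presentation (median 0.12, mean -0.01, test up) and 0.791 for MHC class II presentation (median 0.08). Cxcl9, induced by interferon gamma, was at 88.2 ± 100.6 CPM in controls and 133.1 ± 131.6 after RFA (0.58 ± 1.29 SE, FDR = 0.834). Isg15 (0.90 ± 0.78, FDR = 0.554), Cmpk2 (-1.31 ± 0.80, FDR = 0.424), Irf1 (0.41 ± 0.58, FDR = 0.73) and Ciita (-0.73 ± 0.76, FDR = 0.618) lay within the spread, as did H2-T23 (0.70 ± 0.56, FDR = 0.517), Ctss (0.48 ± 0.52, FDR = 0.627) and H2-Eb1 (-0.35 ± 0.57, FDR = 0.767). Psmb10, an immunoproteasome subunit, was lower in all RFA libraries than in all controls (-2.09 ± 0.57 SE, FDR = 0.185) and was past the threshold in DESeq2. Within both groups the libraries differed. The interferon gamma list summed to 1450 and 768 CPM in control replicates 1 and 2, and to 160 and 135 in replicates 3 and 4. RFA replicates 1 and 2 held 1590 and 1130 CPM, and replicates 3 and 4 held 334 and 92. Sums of the type I interferon, MHC class I and MHC class II lists parted the same libraries, and the reason was not tested. RFA libraries 3 and 4 held almost no acinar counts, and 0 and 2 counts of Xist, described below. Without them the number of lists called higher went from 9 to 17. The 4 interferon and MHC lists were among these with camera adjusted p from 3.5e-05 to 0.0176, and adjusted p = 0.547 for each with an estimated correlation. Of the 11 lists called in either direction with all 8 libraries, 8 kept their call in that fit. Without RFA replicate 1 the type I interferon list was called lower (adjusted p = 0.0158). Without RFA replicate 4 the interferon gamma list was called higher (adjusted p = 0.0261). With an estimated correlation no list was called by camera as any single library was left out (lowest adjusted p = 0.326). By library size only, relative to the shift of all genes, the medians of the type I interferon, interferon gamma, MHC class I and MHC class II lists turned negative (-0.25, -0.31, -0.32 and -0.25).

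The list of heat shock genes, chaperones that respond to misfolded protein, rose by camera with the preset correlation (13 of 15 members with a positive log2 fold change, median 0.49, camera adjusted p = 0.000822), and adjusted p = 0.618 with an estimated correlation. Constitutive Hspa8 was at 156.2 ± 20.5 CPM in controls and 231.5 ± 29.5 after RFA (0.57 ± 0.17 SE, FDR = 0.204). Inducible Hspa1b (1.23 ± 0.34, FDR = 0.185) and its near-identical copy Hspa1a (1.59 ± 0.47, FDR = 0.202) and the co-chaperone Hsph1 (0.86 ± 0.28, FDR = 0.216) followed. In edgeR 0 passed over all genes, 8 higher and 1 lower had an unadjusted p under 0.05, and 4 passed adjusted over the list alone, while DESeq2 called Hspa8 and Hspa1b over all genes. The call was lost by library size only (adjusted p = 0.0716). The haem-degrading enzyme Hmox1 stood at 1.32 ± 0.44 SE (FDR = 0.217).

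Genes of the unfolded protein and integrated stress response fell as a list (10 of 14 with a negative log2 fold change, median -0.76, camera adjusted p = 0.00377), and adjusted p = 0.715 with an estimated correlation. The endoplasmic reticulum proteins Sdf2l1 (-2.34 ± 0.58 SE, FDR = 0.184), Creld2 (-1.84 ± 0.47, FDR = 0.184) and Herpud1 (-1.78 ± 0.47, FDR = 0.184) and asparagine synthetase Asns (-2.83 ± 0.77, FDR = 0.185) led it. In edgeR 6 members passed lower and 1 higher adjusted over the list alone, and 0 passed over all genes, with 7 lower and 1 higher at an unadjusted p under 0.05, while DESeq2 called these 4 and Chac1 over all genes. With the acinar share as a covariate the call was lost (adjusted p = 0.368). Targets of p53 and apoptosis genes were not called (median 0.29, camera adjusted p = 0.412), with the death receptor Tnfrsf10b at 1.01 ± 0.53 SE (FDR = 0.365) and Phlda3 at 1.07 ± 0.58 (FDR = 0.377). Hypoxia and glycolysis genes rose by a narrow margin (14 of 17, median 0.51, camera adjusted p = 0.0475), and adjusted p = 0.828 with an estimated correlation. Its members include the glucose transporter Slc2a1 (0.79 ± 0.33, FDR = 0.287), collagen hydroxylase P4ha1 (0.46 ± 0.20, FDR = 0.31), Pdk1 (-0.76 ± 0.24, FDR = 0.206) and Ndrg1 (-0.80 ± 0.37, FDR = 0.326), of which 0 passed in edgeR or DESeq2 and which overlapped between the groups. The hypoxia call was lost without control replicates 1, 2 or 3 or RFA replicate 4 (adjusted p from 0.0673 to 0.242), with upper-quartile scaling (adjusted p = 0.0602), by library size only (adjusted p = 0.373) and with the acinar share as a covariate (adjusted p = 0.928).

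Lists of proliferation, matrix remodelling and contractile cells rose after ablation by camera with the preset correlation, while fibroblast and endothelial lists were not called. Proliferation genes rose (19 of 19, median 0.77, camera adjusted p = 2.92e-06), and adjusted p = 0.715 with an estimated correlation. Tyms (0.54 ± 0.17 SE, FDR = 0.205), Mcm2 (0.61 ± 0.25, FDR = 0.277), Pcna (0.77 ± 0.31, FDR = 0.28) and Mcm5 (0.96 ± 0.43, FDR = 0.311) act in DNA replication and had all RFA libraries above all controls. Mki67 stood at 0.72 ± 0.59 SE (FDR = 0.53). Extracellular matrix remodelling and wound repair rose (18 of 18, median 0.89, camera adjusted p = 1.9e-05), and adjusted p = 0.618 with an estimated correlation. It was led by gelatinase Mmp9 (1.51 ± 0.48, FDR = 0.21), plasminogen activator inhibitor Serpine1 (2.00 ± 0.75, FDR = 0.252), lysyl oxidase Lox (1.22 ± 0.46, FDR = 0.255) and urokinase Plau (0.76 ± 0.32, FDR = 0.291). Myofibroblast and contractile genes rose (12 of 12, median 0.74, camera adjusted p = 0.000936), and adjusted p = 0.618 with an estimated correlation. Cnn1 (1.68 ± 0.68, FDR = 0.278), Tagln (0.93 ± 0.40, FDR = 0.296), Acta2 (0.98 ± 0.45, FDR = 0.318) and Myl9 (0.78 ± 0.40, FDR = 0.354) encode contractile proteins. In edgeR 0 members of these 3 lists passed over all genes or adjusted over the list alone, with 3, 4 and 2 at an unadjusted p under 0.05, and DESeq2 called 0. By library size only all 3 calls were lost (adjusted p of 0.0716, 0.0718 and 0.0875). The summed CPM of the proliferation and matrix lists had an exact permutation p of 0.0857 each and that of contractile genes 0.0286. Control replicate 3, which held the highest acinar share, 38.6%, stood apart, with a proliferation sum of 88 CPM against 482 to 740 in the other controls and 617 to 992 after RFA. Without it all 3 lists were still called (largest adjusted p = 0.0023), but the median relative to all genes went from 0.73 to 0.43 for proliferation, from 0.85 to 0.65 for matrix remodelling and from 0.70 to 0.42 for contractile genes.

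The tumour epithelium list rose (15 of 17, median 0.64, camera adjusted p = 0.0326), and adjusted p = 0.618 with an estimated correlation. The keratins Krt8, Krt7 and Krt19 stood at 0.79 ± 0.24 SE (FDR = 0.204), 1.38 ± 0.50 (FDR = 0.244) and 0.81 ± 0.52 (FDR = 0.441). The mucosal peptide Tff2 stood at -4.33 ± 0.75 (FDR = 0.184) and Muc1 at -1.09 ± 0.36 (FDR = 0.216). Tff2 was also counted among the 77 exocrine genes that an alternative removed before scaling, and whether its fall came from tumour cells was not tested. Tff2 was the only member to pass adjusted over the list alone, and DESeq2 called Tff2 lower and Krt8 higher. Its level of 1544 ± 1176 CPM in controls against 76.8 ± 57.8 after RFA brought the summed CPM of the list from 2590 ± 961 to 1560 ± 218, opposite to the median. The call was lost without control replicates 1, 2 or 3 or RFA replicate 4 (adjusted p from 0.0513 to 0.114), by library size only (adjusted p = 0.805) and with the acinar share as a covariate (adjusted p = 0.322). Fibroblast genes were not called (median 0.60, camera adjusted p = 0.0875). Among them Mfap5 stood at 0.70 ± 0.28 SE (FDR = 0.279) and Pdgfrb at 0.79 ± 0.33 (FDR = 0.287), and Col1a1 at 0.88 ± 0.54 (FDR = 0.422). The fibroblast list was called higher without control replicate 4 or RFA replicates 2, 3 or 4 (adjusted p from 0.00725 to 0.0482).

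The other tissue lists were not called by camera with all libraries, and DESeq2 called 1 of their members, Saa3. Endothelium had a median of 0.01 (camera adjusted p = 0.753), with Cdh5 at 0.56 ± 0.28 SE (FDR = 0.347) and Robo4 at 0.55 ± 0.36 (FDR = 0.442). Complement and acute phase genes (median 0.17, camera adjusted p = 0.271) included Saa3 (2.35 ± 0.77, FDR = 0.217) and C2 (0.93 ± 0.35, FDR = 0.255), and were called higher without RFA replicate 3 (adjusted p = 0.0342). Red blood cell genes (median -0.89, camera adjusted p = 0.442) included Hba-a1 (-1.10 ± 0.72, FDR = 0.447) and Alas2 (-1.09 ± 0.68, FDR = 0.429). Adipocyte genes (median -0.86, camera adjusted p = 0.271) included Lpl (-1.08 ± 0.36, FDR = 0.221) and Pparg (1.148 ± 0.48, FDR = 0.285), and were called lower without control replicate 2 (adjusted p = 0.0136) or RFA replicate 3 (adjusted p = 0.0362). Schwann cell genes (median 0.18, camera adjusted p = 0.845) included Mbp (-0.87 ± 0.34, FDR = 0.266) and Ncmap (1.00 ± 0.46, FDR = 0.315). Skeletal muscle had 1 tested gene, Tnni2 (0.06 ± 0.64, FDR = 0.971), and keratinocytes had 3, including Dmkn (-0.38 ± 0.62, FDR = 0.764) and Sbsn (-0.20 ± 0.51, FDR = 0.858).

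**Figure D4:**
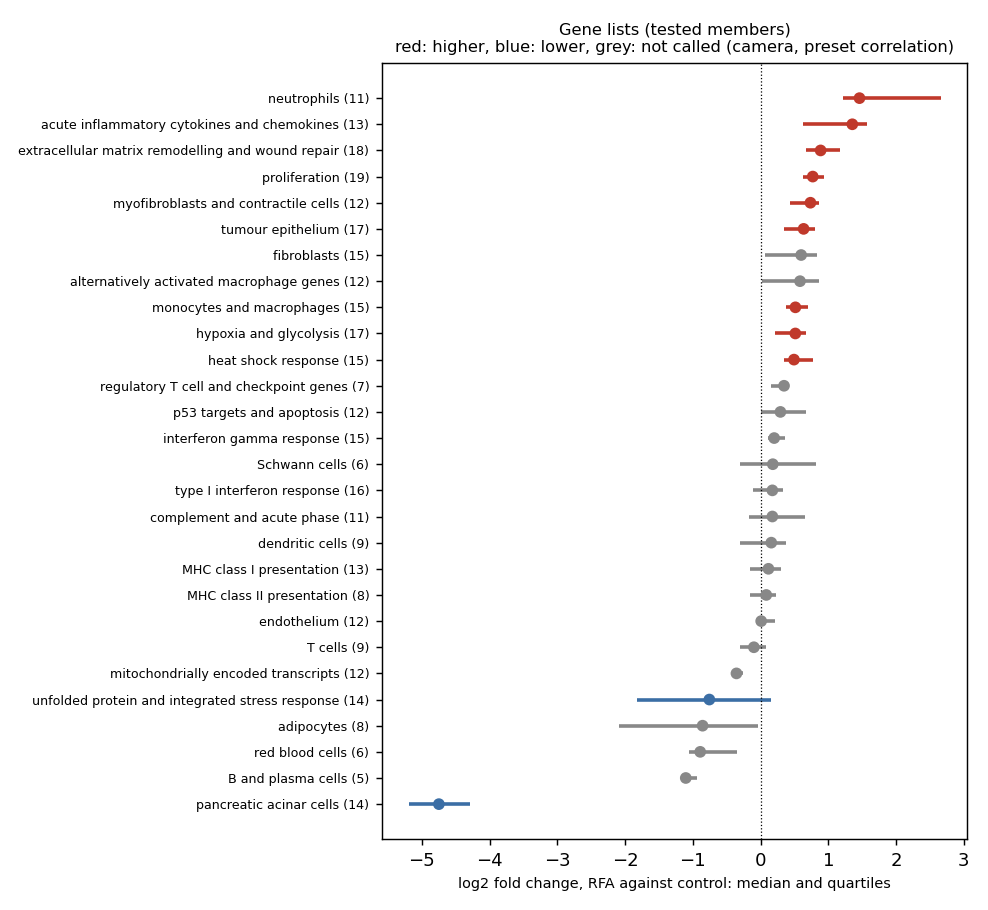
Median (points) and quartiles (lines) of the log2 fold changes of each list's tested members, RFA against control (horizontal axis), with the number of members in brackets. Red lists were called higher and blue lists lower by camera with the preset correlation, and none was called with an estimated correlation. The neutrophil list has the highest median, 1.46, and the acinar list the lowest, -4.75.

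Mitochondrially encoded genes took a larger share of counts after ablation, 11.04% ± 1.68 against 4.96% ± 1.68 in controls (SD, n = 4 each, exact two-sided permutation p = 0.0286). Without control replicate 3 the exact permutation p was 0.0571, although every RFA library still lay above every remaining control. After TMM scaling 0 of their 12 tested genes had a positive log2 fold change (median -0.36, camera adjusted p = 0.162), among them mt-Atp6 (-0.41 ± 0.20 SE, FDR = 0.344) and mt-Nd6 (-0.52 ± 0.28, FDR = 0.373). Counted outside 77 exocrine genes, the share differed by -0.78 percentage points (exact permutation p = 0.4), so the direction depended on the denominator.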

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

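The tests of islet genes, non-enzyme acinar genes, list contrasts, the acinar covariate, the exocrine denominator and the signs of mitochondrial genes, and the use of the planned fit without RFA replicate 1 as a test, were chosen after the result was seen. For each reported measure, list and named gene, a library was picked out when its gap to the nearest other library of its group of 4 exceeded 0.829 of the group's range. Of 286 groups checked, 17 were picked out, 5.94% where chance gives 5%.

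Each entry gives that ratio, then the library's log2 CPM against the range of the other 3. Control replicate 3 was the lowest control for Mki67 (0.884, at 2.25 against 5.39 to 5.8), Mcm2 (0.928, at 2.55 against 3.65 to 3.74) and Mmp9 (0.918, at 2.41 against 2.92 to 2.97). It was also lowest for Ppbp (0.863, at -1.94 against 0.194 to 0.533) and Ncmap (0.833, at 0.466 against 1.82 to 2.1). Over whole lists it was lowest for matrix remodelling (0.835, at 1.59 against 4.35 to 4.89) and for p53 and apoptosis (0.834, at 2.74 against 3.56 to 3.72). RFA replicate 1 was the highest RFA library for the neutrophil list (0.882, at 4.64 against 2.57 to 2.82), S100a8 (0.846, at 8.18 against 5.2 to 5.66) and Mmp8 (0.884, at 3.49 against 1.11 to 1.39). It was also highest for the p53 and apoptosis list (0.942, at 4.6 against 3.54 to 3.6). RFA replicate 2 was highest for Hsph1 (0.858, at 5.62 against 4.99 to 5.08) and lowest for Hba-a1 (0.956, at 5.87 against 6.95 to 7). RFA replicate 4 was lowest for Ciita (0.839, at -1.26 against 0.979 to 1.41). Control replicate 2 was lowest for Cdh5 (0.875, at 2.14 against 3.02 to 3.15), control replicate 1 highest for Cr2 (0.913, at 2.66 against 0.958 to 1.11) and control replicate 4 lowest for Ccr3 (0.843, at -0.448 against 1.11 to 1.4).

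For the lower acinar transcripts, the explanation that acinar cells were present and had lost their enzyme transcripts alone was argued against. The 10 acinar genes that encode no enzyme, such as the transcription factors Ptf1a and Rbpjl, had a median log2 fold change of -3.74, against -4.75 for the acinar list. Acinar cells that lost their identity would lose these genes too, so that stays open. Less normal pancreas in the RFA pieces remains a candidate explanation, since 9 of 9 tested islet genes were also lower, with a median of -3.16. Whether RFA destroyed acinar cells or less normal pancreas was collected was not tested and stays open.

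For the higher neutrophil and inflammatory lists, an effect of RFA replicate 1 alone cannot be decided by the list test. Without that library both lists stayed called with the preset correlation (larger camera adjusted p = 0.00419). They were not called with an estimated correlation (camera adjusted p = 0.772). Lists were called under many divisions of the libraries with the preset correlation, so a kept call says little. Without RFA replicate 1 the neutrophil ratio of RFA to control means went from 4.67 to 2.25, a smaller rise in the same direction. For more blood in the RFA pieces, the red blood cell genes gave no sign of a rise. Of 6 tested, 0 had a positive log2 fold change (median -0.89). Summed over that list, CPM was 1440 ± 1380 in controls and 905 ± 404 after RFA (SD, exact permutation p = 0.657). This fall was within the spread, so more blood cannot be excluded. The rise of the neutrophil and inflammatory lists over red blood cell genes, 2.08 log2 units, was within the spread too (exact permutation p = 0.143). A trend with the acinar share as the whole cause cannot be told apart. Both lists stayed called with that share as a covariate (larger camera adjusted p = 1.51e-05, and adjusted p = 0.417 with an estimated correlation). The shares of the groups do not overlap, however, so this fit cannot separate group from share. More tumour in the pieces cannot be told apart either, since the rise over tumour epithelium genes, 1.21 log2 units, had an exact permutation p = 0.114. An inflammatory response to ablation stays open beside these.

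For the higher mitochondrial share, more mitochondrial RNA per cell could not be tested, because scaled counts are relative to other genes and not to cells. Relative to other genes there was no rise, since 0 of 12 tested genes had a positive log2 fold change after TMM scaling. Their median relative to all genes was -0.15 by library size only. Exocrine transcripts taking much of the control counts are a candidate explanation, because outside 77 exocrine genes the difference was -0.78 percentage points. Those genes took from 0.0215% to 78.3% of a library's counts. An effect of RFA on mitochondrial transcripts was not tested in any other way.

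The edgeR count of genes past the threshold was 0, so all 35 of 35 divisions were bound to give as many (highest other count 0) and this says nothing about chance. Chance could not be excluded for the other counts. Genes with an unadjusted p under 0.05 numbered 2118, and 2 of 35 divisions gave as many, the highest other count being 2881 for control replicate 1 with RFA replicates 2, 3 and 4 against the rest. Called lists numbered 11, and 23 of 35 divisions gave as many, with a highest other count of 21. Lists were thus called under many divisions with the preset correlation of 0.01, where the estimated one had a median of 0.444 over the called lists, and whether this or a structure of the samples was the reason was not tested.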

How the results depend on the processing

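The covariate, the removal of exocrine genes, the joint removal of libraries, the estimated correlation with libraries left out, library-size scaling and no filter for lists, and the alternatives of the acinar share were chosen after seeing the data. In the fits not named here the count of called genes was 0 in each direction, and the cause of the changes below was not tested. Genes higher and lower numbered 67 and 584 by DESeq2, 64 and 630 by limma-voom, 5460 and 58 by library size only, 9587 and 166 by limma on log2(TPM + 1), 1 and 0 with the acinar covariate (Lcn2), and 1 and 1 without control library 3 and RFA libraries 3 and 4 (Gm2663 and Cela3a, Gm2663 being named after its value was seen). They ranged from 0 to 10 and from 0 to 262 as each library was left out. The median log2 fold change moved to 1.41 by library size and 1.17 by TPM. Relative to that shift, 3 and 8 of 108 named genes changed sign, Cd8a under both. Lists higher numbered 16 with the covariate, 17 without RFA libraries 3 and 4, 16 without control 3 too, 1 by library size, and 0 by fry or with an estimated correlation. Left-out libraries gave 7 to 12. Lists lower numbered 7 by library size, 4 with no filter, 1 with exocrine genes removed (which removes the acinar list), and 0 by fry or with an estimated correlation. With exocrine genes removed, 9 of the 10 called lists that could still be tested kept their call. Left-out libraries gave 2 to 4. The hypoxia list median turned to -0.009 without control 3 and RFA 3 and 4. Replicate numbers did not pair the libraries (correlations of same-numbered deviations -0.24, 0.08, -0.29 and 0.24). The replicate block gave 0 genes in each direction, 10 lists higher and 2 lower. The PC1 difference of 72.7 was 98.3 over all tested genes and 58.2 to 86.6 as libraries were left out. The mitochondrial difference of 6.08 percentage points turned to -0.78 outside exocrine genes and ranged from 5.50 to 6.89 as libraries were left out. The acinar difference of -26.4 points was -21.9 without RFA 3 and 4 and -19.3 without control 3 too, where the smaller groups allow no exact p under 0.05, and ranged from -30.3 to -23.8. The group difference in total counts per library kept its side of the threshold throughout. Foxp3, Cd3e, Ly6g and Il6 did not pass the filter.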

Other observations

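The gene lists, tests and comparisons in this part were chosen after the values were seen, apart from the 34 lists and the divisions of the libraries. Islet hormone genes were lower in every RFA library than in any control when summed, at 561 ± 339 CPM in controls and 44.3 ± 42.1 after RFA (SD, n = 4 each, exact permutation p = 0.0286). Ins2 stood at a log2 fold change of -4.47, Ins1 at -3.74, Gcg at -3.48 and the granule protein Chga at -3.76. Regenerating-family genes, which encode proteins secreted by injured or inflamed pancreas, had 6 tested members with a median of -1.02, with Reg1 at -2.97 but Reg3b at 0.03 and Reg3g at 0.27, and summed CPM did not part the groups (exact permutation p = 0.114). Their share of counts was 7.3% in RFA replicate 1 against 3.036% to 3.596% in controls, 3.65% in RFA replicate 2, 0.00338% in RFA replicate 3 and 0.117% in RFA replicate 4. RFA replicates 3 and 4 also held the lowest acinar shares, 0.00876% and 0.104%. Whether the regenerating-family genes followed injury or tissue content was not tested.

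With the acinar share as a covariate, the neutrophil list had a median 2.14 above that of all genes (camera adjusted p = 7.17e-15, and adjusted p = 0.417 with an estimated correlation). In that fit Lcn2 was the single gene past the threshold (4.72 ± 0.46 SE, edgeR FDR = 0.0492). The acinar shares of the groups do not overlap, so the fit cannot show a rise apart from that share. Over the 35 divisions of the libraries, the real one gave the largest absolute list median for the acinar, heat shock, acute inflammatory and matrix remodelling lists (1 of 35 each), while 2 divisions, the real one included, gave a median as large for neutrophils, tumour epithelium and contractile cells, 4 for proliferation, 7 for hypoxia and for the unfolded protein response, and 9 for monocytes and macrophages.

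Xist, which is transcribed from the inactive X chromosome of females, was at 183, 274 and 516 CPM in control replicates 1, 2 and 3 and at 332 and 122 CPM in RFA replicates 1 and 2. It was at 4.26 CPM in control replicate 4, at 0.157 in RFA replicate 4 and had 0 counts in RFA replicate 3. Counts of 4 Y-linked genes (Ddx3y, Eif2s3y, Kdm5d and Uty), summed, ran from 5 in control replicate 3 to 1277 in RFA replicate 4. Kdm5d and Uty had 0 counts in control replicate 3. The labels give no sex. Xist and Y-linked transcripts differed between libraries of both groups, and their bearing on the comparison of RFA with control was not tested.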
